A study of Schizosaccharomyces pombe with 8 samples.

How the data were processed

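Fission yeast cells (Schizosaccharomyces pombe) of genotype pat1-114 rec12Δ were taken through synchronous meiosis. The pat1-114 mutation is a temperature-sensitive allele that lets meiosis be started by a temperature shift, and the rec12 deletion removes the protein that makes meiotic DNA breaks. Per the labels' protocols, cells were held without nitrogen for about 18 h, meiosis was started by adding nitrogen and shifting to 34 °C, and cells were harvested at 3.5 h. Cultures of 500 mL were fixed with formaldehyde at 1%, and GFP-tagged Rec27 was immunoprecipitated from chromatin sheared to about 1000 bp. Rec27 is a component of the linear elements, the protein axis of fission yeast meiotic chromosomes. In the interacting library the immunoprecipitate was ligated while still crosslinked, so that DNA held together in the cell could be joined. In the de-crosslinked library the crosslinks were removed before ligation, so that it serves as the control for joining without crosslinks. Both were amplified with a Sequenase kit and made into Nextera libraries after fragmentation to about 300 bp, per the labels' protocols.

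The series holds 8 samples, and 2 libraries were analysed, both of Rec27-GFP with rec8 present, 1 per group. The other 6, which are Rec27-GFP in a rec8 deletion, Rec25-FLAG and Rec27-FLAG, were not analysed here. The deposited tables hold 1 line per ligated pair of DNA ends, with the chromosome and position of each end and the authors' class of hot or cold for each end. CASAVA 1.8.0 is named in the submitters' processing notes; the aligner, its settings, the genome build and the rule behind hot and cold are not stated in the sources used here. Counts were made here by counting lines of these deposited tables. Pairs on 1 chromosome start at 1999 bp, the smallest distance in either table.

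Positions were checked against the RefSeq assembly ASM294v3. Stretches of that assembly without a unique 50 bp word, 276 stretches of 448340 bp in all, held 0 ends of the 2 libraries, against 968 and 629 ends when the positions were moved by -100 and 100 bp. The largest position on chromosome II lies 22 bp past the end of the assembly's sequence. Positions are given below as the tables give them, with the genes of ASM294v3.

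Single ligation junctions were amplified before fragmentation, so that 1 junction appears as many pairs with slightly different ends. Of the pairs between chromosomes, 76.3% in the interacting and 72.0% in the de-crosslinked library had another pair with both ends within 500 bp, against 1.06% and 0.957% after the partners were shuffled. Pairs linked in this way were therefore also counted once, as ligation events. This was chosen after the data were seen. Exact repeats of a pair made up 1.36% and 0.950% of pairs.

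All other choices named here were made before the data were examined unless stated. Hotspots were 1 kb bins with at least 10 times the ends of the median bin in the de-crosslinked library (150 ends), merged across a gap of 1 bin. The genes named are those at the 20 hotspots with most ends in that library, those at the 20 hotspot pairs at least 20 kb apart with most pairs in the interacting library, and members of the fixed gene lists that overlap a hotspot. The authors' hot class was used as a second definition after the hotspots proved too few for distances; runs of hot ends over both tables were taken as 1 hot region each. Comparisons of pairs used those 5 kb apart or more, above the size of a sheared fragment, and pairs between chromosomes. The random level was the mean of 1000 seeded shuffles that joined each library's own ends at random, which keeps the number of ends at every place; alternatives used 200 shuffles. Shares have exact Clopper-Pearson 95% intervals and counts have exact Poisson intervals. Libraries were compared with two-sided Fisher's exact tests on pair or event counts. With 1 library per group these tests compare the libraries, not the conditions, and intervals cover counting error at most. Counts of pairs and ends treat copies of 1 junction as independent molecules, with 2.87 pairs per event in the interacting and 2.20 in the de-crosslinked library. Their intervals are therefore too narrow and their p-values too small. Counting events lessens this as far as copies were merged.

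The loss of pairs with distance was compared between hot and cold DNA as a log2 odds ratio, of pairs 20 to 200 kb apart over pairs farther apart or on different chromosomes, in the interacting over the de-crosslinked library, with a block jackknife over 127 segments of 100 kb. For gene lists, the median ends per kb over the gene and 500 bp on each side was set against 10000 random lists of genes matched on length, leaving out genes whose window is under 0.5 unique. These list densities divide by the whole window, including any part that is not unique and can hold no ends. Overlap of a list with the hot class was tested by two-sided Fisher's exact test with Benjamini-Hochberg adjustment over 5 lists. The annotation marks no centromeres, so the stretch of each chromosome richest in repeats was used for them, chosen after the data were seen. Chromosome ends were the outer 100 kb. The draws of gaps by length and the hot less cold values within each library were also chosen after the data were seen. The plan made beforehand named odds per distance class, and the single window of 20 to 200 kb was not in it. Neither was the test of list overlap with the hot class.

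The counting code was tested on simulated libraries made from the real ends. Random pairs gave 1.00 times the random level at 50 to 100 kb for the interacting simulation of 29985 pairs and 1.01 for the de-crosslinked one of 29988. Random pairs that were each copied a random number of times collapsed to 99.9% and 99.8% of the events they were made from. These simulated copies were all placed closer together than the 500 bp window, so they had to merge. The simulation therefore cannot show whether real copies, which may spread wider, were all merged. Its pairs were also joined at random, without the many short joins of the interacting library. It therefore cannot show whether distinct events that lie close together were merged into 1. Alternatives covered repeated pairs, the smallest distance, each chromosome left out, the hotspot threshold, source and bin size, libraries thinned to the same number of pairs or of events, removal of the 1% of bins with most ends, the distance limits, the end windows and the gene flanks. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, Biopython 1.88, matplotlib 3.10.9 and BLAST 2.17.0 were used.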

Results

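The series title asks about long-distance communication along meiotic chromosomes. The data are pairs of DNA ends joined by ligation in Rec27-GFP immunoprecipitates of meiotic fission yeast, in 2 libraries with no replicate. The interacting library, ligated while crosslinked, held 101984 pairs, which came from 35511 ligation events. The de-crosslinked library, ligated after crosslink removal, held 123434 pairs from 56018 events. The median 1 kb bin held 12 ends in the interacting and 15 in the de-crosslinked library. The ends followed chromosome length, with 44.8% and 44.7% on chromosome I, which is 44.4% of the genome. The deleted gene rec12 (chromosome I, 1772925 to 1774203) held 1 end in each library, whereas rec8, the meiotic cohesin gene, held 36 in the interacting and 34 in the de-crosslinked library.

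The first comparison asked where the ends of the Rec27-GFP immunoprecipitates lay on the chromosomes. None of the 8 samples is an input or untagged library. Binding of Rec27 could therefore not be told apart from other sources of high counts, here and below. The place with most ends was on chromosome I, 1149001 to 1154000, over mug115, SPAC56F8.13, SPAC56F8.15 and esc1, with 1833 ends in the de-crosslinked library (95% Poisson interval 1750 to 1919) and 854 in the interacting one. It was followed by gti1, between tup12 and loc1 (chromosome I, 380001 to 383000, 1218 and 521 ends), and by the gap next to ste11, the master transcription factor gene of sexual differentiation (chromosome II, 3980001 to 3984000, 1170 and 470 ends). The next were gsf1 (chromosome II, 3009001 to 3012000, 906 and 405 ends), hsr1 (chromosome I, 1955001 to 1958000, 844 and 472 ends) and SPCC1235.17 between the hexose transporter genes ght6 and ght5 (chromosome III, 208001 to 211000, 747 and 443 ends). The other 14 of the 20 hotspots with most ends in the de-crosslinked library lay at pdc201, fhn1, pfl2, rgp1 and ssn6, SPAC17A2.11, ymc1, the end of chromosome II beyond tlh2, mug114 and hxk2, ubp11, ste7, the gap between cup1 and eno101, SPCC1739.08C, SPAC22F8.03C and the gap between ole1 and gst4. These 20 held 374 to 1833 ends each in that library. Their order is by total ends, whatever the width. Per kb in that library, the gti1 hotspot was higher than that over mug115 and esc1, at 27.1 and 24.4 times the median bin.

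**Figure D1:**
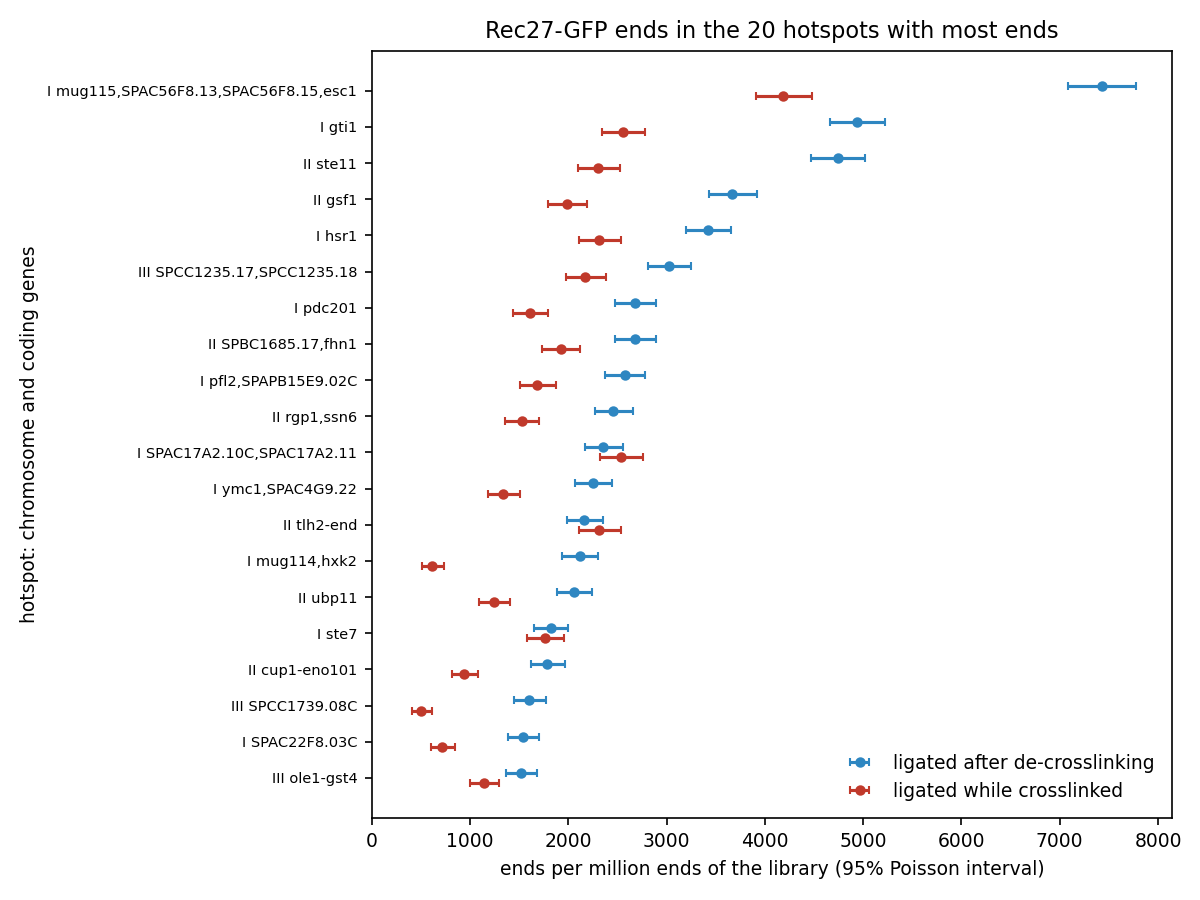
Rec27-GFP ends, scaled to the total ends of each library (horizontal axis), in the 20 hotspots with most ends in the de-crosslinked library, named by chromosome and by the coding genes they overlap or lie between; points are the 2 libraries and bars are 95% Poisson intervals. The hotspot over mug115 and esc1 has the most ends in both libraries, and 18 of the 20 are lower in the interacting library.

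In all, 50 hotspots covered 89 kb, 0.708% of the genome, with 22 on chromosome I, 21 on chromosome II and 7 on chromosome III. The summits of 45 of them lay in the 451 regions the authors class as hot, whose median width is 5314 bp and which cover 22.9% of the genome. Hotspots held 8.24% of the ends in the de-crosslinked library (8.13 to 8.35) and 5.41% in the interacting library (5.32 to 5.51), and 44 of the 50 had a smaller share of the ends in the interacting library. Since these places were picked for high counts in the de-crosslinked library, that order is partly set by the choice: with hotspots called in the interacting library instead, the shares were 5.02% and 5.09%. The authors' hot regions held 38.4% of de-crosslinked and 33.4% of interacting ends. Across 12573 bins of 1 kb, which are not independent replicates, the 2 profiles had a Pearson r of 0.55 and a Spearman rho of 0.34 on log2 ends scaled to each total.

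Some hotspots, such as SPBC359.01 and aat1 (chromosome II, 106001 to 107000 and 111001 to 112000) rested on few junctions. They held 272 and 270 ends in the de-crosslinked library, but only 10 and 7 ends once copies of a junction were counted once. Likewise glm1 (162 ends), sdo1 (153 ends) and pst1 (172 ends) fell to 9, 10 and 9 ends in that library, whereas the hotspot over mug115 and esc1 kept 762 and that next to ste11 kept 501.

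The second comparison asked which genes lie at these places. Hotspots of ends lay mostly between protein-coding genes. Of 50 summits, 35 or 70.0% (55.4 to 82.1) were outside protein-coding genes, against 23.3% of the genome. So were 64.7% of the midpoints of the authors' hot regions. Without an input library this cannot be assigned to Rec27 alone. The 31 gaps between coding genes that held a summit had a median length of 2532 bp. As many gaps drawn by length from all 3940, since a random place falls in long gaps more often, had a median of 1296 bp (95% of 1000 draws within 874 to 1942). In the de-crosslinked library the density of ends was 30.1 per kb in long noncoding RNA genes outside coding genes and 19.1 per kb in protein-coding genes, and in the interacting library it was 22.0 and 16.1. DNA with no annotated gene held 19.6 ends per kb in the de-crosslinked and 16.6 in the interacting library, near the values of protein-coding genes. The higher density outside coding genes therefore lay in annotated long noncoding RNA genes. tRNA genes were low, with 7.17 and 7.75 ends per kb in the de-crosslinked and interacting libraries.

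Among the gene lists, the highly expressed housekeeping genes stood out in both libraries. Their median was 24.5 ends per kb in the de-crosslinked library against a median of 15.8 for random lists of like gene length (above 99.98% of the lists), and 20.7 against 13.5 in the interacting library (above 99.74%). Members with most ends per kb were tdh1, which encodes glyceraldehyde-3-phosphate dehydrogenase, at 5.41 times the median gene in the de-crosslinked library, adh1, an alcohol dehydrogenase gene, at 4.80 times, and eno101, which encodes enolase, at 4.35 times. Of this list 14 of 17 genes overlapped the authors' hot class, where random lists had a mean of 5.49 (two-sided Fisher's exact test, adjusted p = 0.000103). Of the stress genes with binding sites for the transcription factor Atf1-Pcr1, 9 of 11 overlapped it (Fisher's exact test, adjusted p = 0.00204), among them atf1 itself, gpd1, ctt1 and hsp16. The median of the stress list lay above 99.07% of random lists in the interacting library and above 78.49% in the de-crosslinked library.

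The genes for linear element and DNA break proteins gave no such overlap, with 2 of 16 in the hot class (rec7 and rec12, which is deleted here; Fisher's exact test, adjusted p = 0.290). By the same exact test, the genetic markers had 7 of 17 (adjusted p = 0.542) and the meiotic regulators and middle genes 4 of 14 coding genes (adjusted p = 1). Single members of these lists were high: ade6, an adenine synthesis gene and common recombination reporter, had 5.69 times the median gene in the de-crosslinked library and 4.59 times in the interacting one, and ste11 had 5.61 and 4.68 times. Of the named genes of the lists, ste11 overlapped a hotspot and eno101 touched one with its 500 bp flank only. The medians of the linear element list lay above 80.1% of random lists in the de-crosslinked and 21.3% in the interacting library. Those of the marker list lay above 47.6% and 43.9%, and those of the meiotic list above 90.7% and 46.7%. The meiotic list moved to 99.55% in the de-crosslinked library without flanks, past the 95% range of random lists, and to 95.5% as events. Counted as events, the linear element list fell to 11.15% and the marker list to 13.4% in the de-crosslinked library, so that the place of these lists depends on the counting. With flanks of 500 bp the tRNA genes lay below every one of the random lists in both libraries, but with flanks of 1 kb they lay above 15.5% of them in the interacting library. Only 130 of 171 tRNA genes had windows unique enough to measure. Sequence that is not unique in the remaining windows may lower their place, and its share in it was not tested. The long noncoding RNA genes taken whole had no stable place, above 37.6% and 2.11% of the lists in the de-crosslinked and interacting libraries, 97.35% and 38.95% with flanks of 1 kb, and 0% in both as events. The subtelomeric and mating type genes tlh1, tlh2, mat1-Mc and mat3-Mc could not be measured because their sequence is not unique.

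The third comparison asked how the immunoprecipitated DNA was joined when crosslinks were kept. DNA was joined within its own chromosome more often, and to the other chromosomes less often, in the interacting library. Pairs between chromosomes made up 54.7% (54.4 to 55.0) of its pairs, against 62.9% (62.7 to 63.2) in the de-crosslinked library, a difference of -8.22 points; random joining of the same ends gave 63.4% and 63.2%. Counted as events the shares were 57.0% and 62.9% (two-sided Fisher's exact test, p = 2.99e-69). Within a chromosome, 32.1% (31.7 to 32.6) of the pairs lay within 100 kb in the interacting library and 4.92% (4.72 to 5.12) in the de-crosslinked one, where random joining gave 4.13% and 4.11%. Counted as events the shares within 100 kb were 24.5% and 4.51%. This held on each chromosome: for events it was 21.1% against 3.88% on chromosome I, 25.5% against 4.31% on chromosome II and 36.5% against 8.62% on chromosome III. The libraries have no replicates, so the spread between cultures is unknown.

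Events of the interacting library lay 22.4 times above random at 5 to 10 kb, 14.8 times at 10 to 20 kb, 7.58 times at 20 to 50 kb and 3.07 times at 50 to 100 kb. At 100 to 200 kb the value was 1.22 (1.13 to 1.32), and at 200 to 500 kb it was 0.884 (0.838 to 0.932), near the 0.873 seen between chromosomes. In the de-crosslinked library it was 1.96 at 5 to 10 kb, 1.26 at 10 to 20 kb, 1.06 at 20 to 50 kb and 0.980 at 50 to 100 kb.

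The fourth comparison asked whether hotspots of ends in the Rec27-GFP immunoprecipitates are joined to each other over distance, the question of the title. Of the events that joined 2 of the authors' hot regions on a chromosome, 30.0% (28.0 to 32.0) lay within 200 kb in the interacting library. In the de-crosslinked library 7.16% (6.30 to 8.11) did, and random joining gave 7.75% and 7.53%. These were 622 of 2075 and 233 of 3252 events (Fisher's exact test, p = 1.25e-106). Joining within 200 kb was not particular to hot regions. With every pair counted, the shares were 40.7% and 7.34% for pairs of hot regions. For all pairs on a chromosome they were 36.7% and 9.02%. The test therefore compares the libraries and does not set hot regions apart from other DNA. In the interacting library hot regions were joined to each other 9.70 times above random at 20 to 50 kb (8.37 to 11.2), 4.98 times at 50 to 100 kb (4.24 to 5.81) and 1.70 times at 100 to 200 kb (1.40 to 2.05). Cold DNA was joined to cold DNA 7.73 times above random at 20 to 50 kb, 2.79 times at 50 to 100 kb (2.49 to 3.11) and 1.23 times at 100 to 200 kb. Pairs with 1 hot end had 6.92, 2.85 and 1.09 times. In the de-crosslinked library hot regions were joined to each other 1.21, 0.796 and 1.03 times the random level at these distances, and cold DNA to cold DNA 1.25, 1.17 and 1.04 times.

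**Figure D2:**
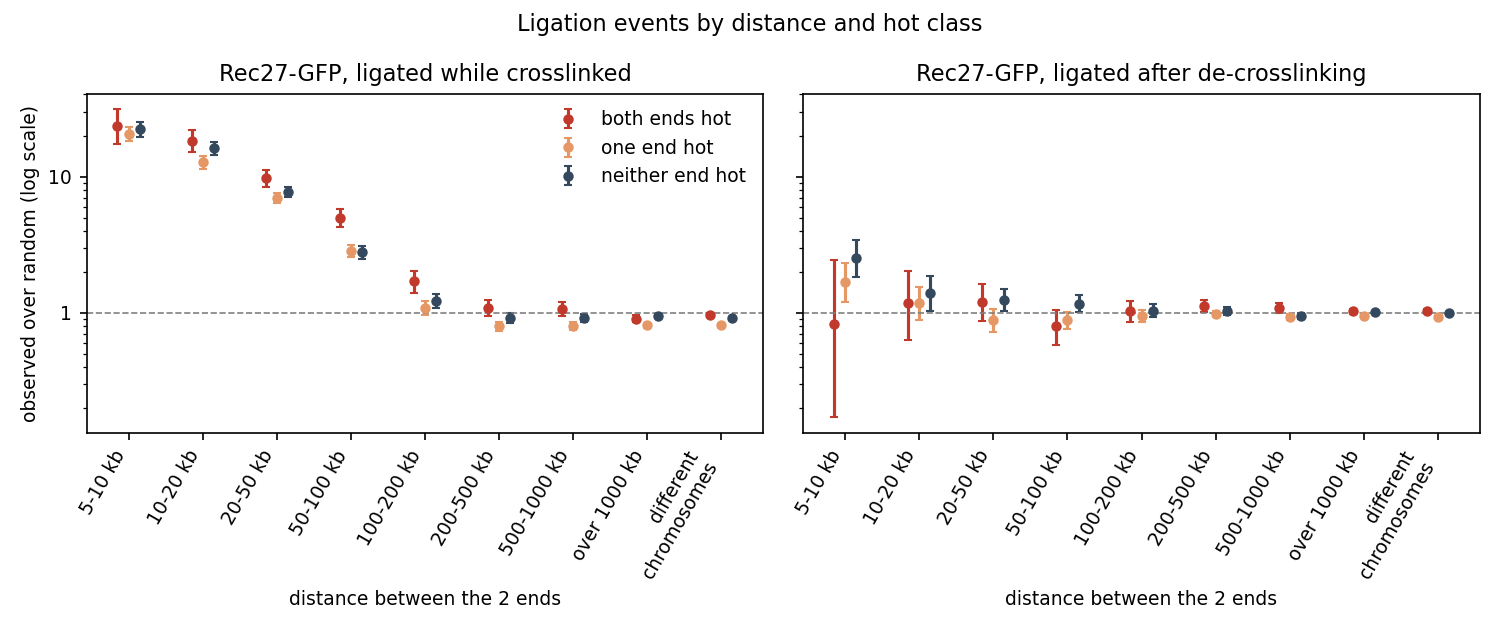
Ligation events, observed over the random level on a log axis, by the distance between the 2 ends, for the interacting library on the left and the de-crosslinked one on the right; colours give pairs with both, 1 or no end in the authors' hot regions, and bars are 95% Poisson intervals. At 50 to 100 kb in the interacting library the pairs with both ends hot sit at 4.98 and those with neither at 2.79, while at 5 to 10 kb the intervals of all 3 classes overlap.

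The log2 odds ratio of the interacting over the de-crosslinked library, for events 20 to 200 kb apart over those farther apart, was 2.12 ± 0.14 (jackknife SE) for pairs of hot regions, 1.70 ± 0.10 with 1 hot end and 1.42 ± 0.10 for cold DNA. The difference between the first and the last was 0.70 ± 0.17, and 0.97 ± 0.30 when every pair was counted. Part of it came from the control. Within each library, hot less cold values were taken for events 20 to 200 kb apart over those farther apart, each over random joining. These log2 values were 0.42 ± 0.08 (counting SE) in the interacting library and -0.21 ± 0.11 in the de-crosslinked one. With the 50 hotspots chosen for this question beforehand, the same difference was -0.45 ± 2.39 over all pairs, so that no difference could be detected there in either direction.

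These 50 hotspots were too few for distances. The share of hotspot pairs on a chromosome within 200 kb was 44.6% of 267 pairs in the interacting library (38.5 to 50.8) and 9.24% of 628 in the de-crosslinked one (Fisher's exact test, p = 3.09e-31), but these were 10 of 62 and 6 of 170 events (p = 0.00199). Of the pairs within 200 kb, 71 of 119 and 27 of 58 joined SPBC359.01 to aat1, and without them the shares were 24.5% of 196 and 5.16% of 601 pairs. With hotspots called in 2 kb bins the shares were 1.69% and 0.382% (Fisher's exact test, p = 0.229), and at a limit of 500 kb they were 49.1% and 42.0% (p = 0.0560). In the de-crosslinked library 129 of the pairs within 500 kb joined glm1 to sdo1 in 1 event. Without these the shares were 49.1% and 27.1% (Fisher's exact test, p = 1.84e-09), without SPBC359.01 with aat1 as well they were 30.6% and 22.9% (p = 0.0399), and as events they were 25.8% and 18.8% (p = 0.273). Over all distances and between chromosomes, hotspots were joined to each other 1.87 times (1.71 to 2.03) above random in the interacting and 1.61 times in the de-crosslinked library. The order of the libraries was not stable: with pairs from 20 kb the values were 1.56 and 1.58, without chromosome I they were 1.44 and 1.54, and with hotspots called in the interacting library they were 4.88 and 1.77.

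The 20 hotspot pairs with most pairs in the interacting library each rested on 1 or 2 events, and 17 of them on 1. The first were gti1 with hsr1 (21 pairs, 1 event, 1575 kb apart on chromosome I), ymc1 with SPAC1786.04 and plb2 (17 pairs, 1 event, 742 kb) and pex7 with SPAC22F8.03C (15 pairs, 1 event, 66 kb). In the de-crosslinked library the first had 11 pairs from 4 events, and the others had 0 pairs. The remaining ones included joins of ste7, pas1, pdc201, SPAC17A2.11, mug115, pfl2 and mug114 on chromosome I, the gaps at eno101 and tdh1, ssn6, nep2 and ubp11 on chromosome II, and SPCC1235.17 with the gap between dis1 and pil1 on chromosome III. Of the 20, 12 had no pair in the de-crosslinked library, and 4 lay within 200 kb. No single pair of these hotspots could therefore be resolved at this depth.

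The authors' hot regions give more pairs to look at; those named next were chosen after their values were seen. Of 2868 pairs of hot regions 20 to 200 kb apart, 27 were joined by 3 or more events in the interacting library and 5 in the de-crosslinked one. The pair with most events joined the regions of isp7 and mal2 and of cdc22 and fio1 (chromosome I, 4175882 to 4186894 and 4228898 to 4249981), with 8 events (95% Poisson interval 3.45 to 15.8) against 1 in the de-crosslinked library. The regions of rps3001 and mae1, of gsk3 and hem13, of alp4 and orc1, and of isp4 and scr1 had 5 events each, against 0, 1, 2 and 2. The ste11 region (chromosome II, 3977841 to 3985739) and the region of git11 and gpd1 (4030834 to 4035748) were joined by 3 events, against 1. The second region holds only the edge of gpd1 (4035566 to 4037342). All 3 events ended outside gpd1 and outside ste11 (3983376 to 3987400). Among the 3, the event at 3982742 and 4034291 lies close to that at 3982861 and 4035250. Their ends are nearer than the sheared size of about 1000 bp, so they may be copies of 1 junction.

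**Figure D3:**
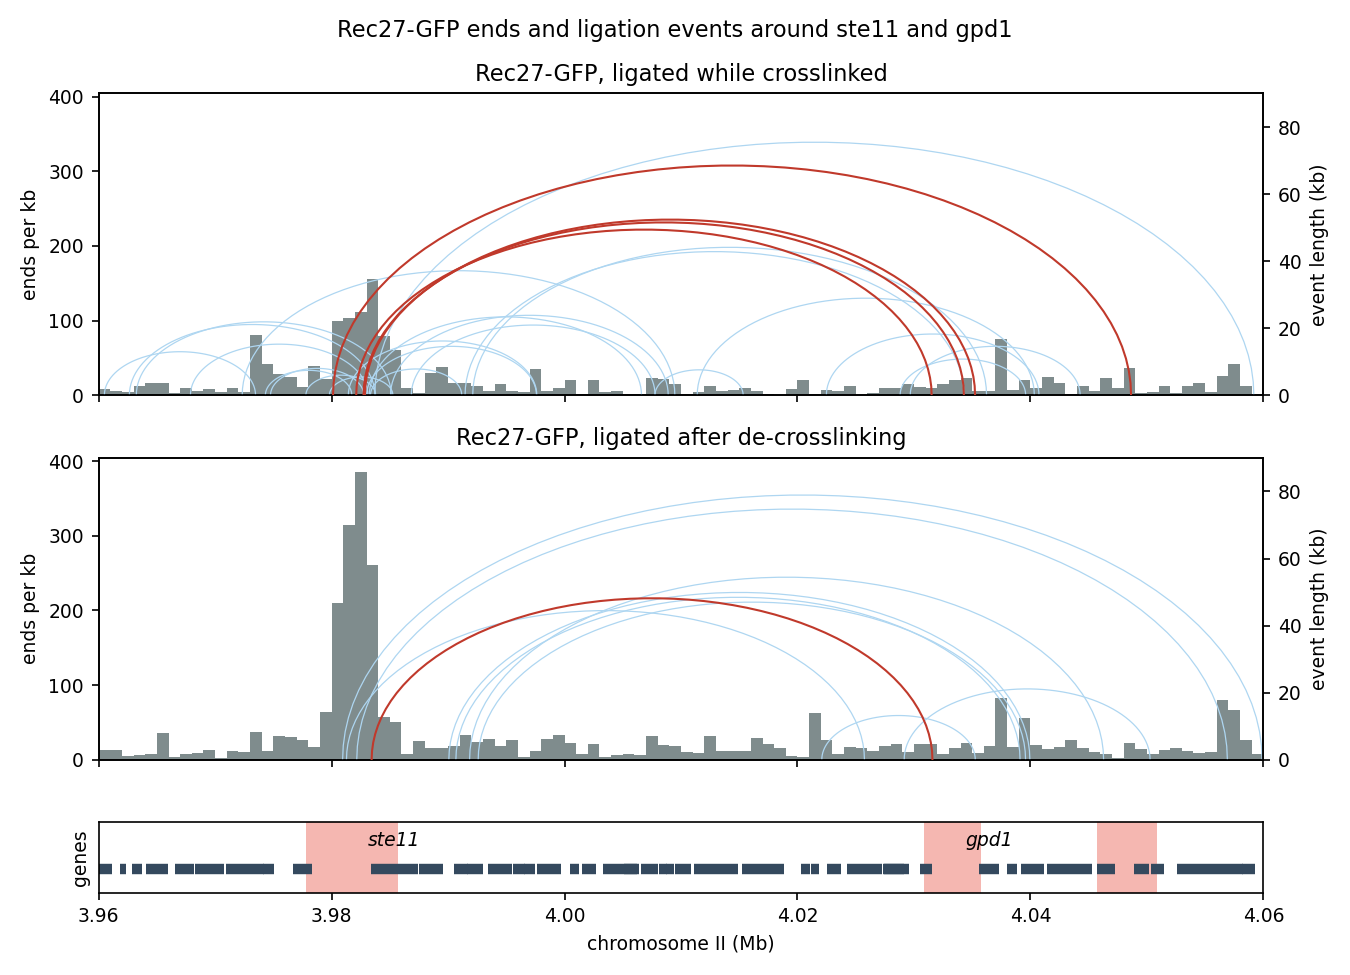
Rec27-GFP ends per 1 kb bin, counting every pair (grey bars, left axis), and ligation events of 5 kb or more with both ends in the window (arcs, height on the right axis in kb) on chromosome II from 3960000 to 4060000, for the interacting library above and the de-crosslinked one below; red arcs join 2 of the authors' hot regions, which are shaded below with the coding genes. The interacting library has 27 events here, 4 of them between hot regions, and the de-crosslinked library has 10, with 1 between hot regions.

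The last comparison asked whether chromosome ends, or centromeres, were joined to each other across chromosomes. Pairs between the outer 100 kb of different chromosomes were 3.36 times (2.99 to 3.75) the random level in the interacting library and 1.28 times (1.06 to 1.53) in the de-crosslinked one. Counted as events they were 1.55 times (1.15 to 2.04; 51 events) and 1.18 times (0.889 to 1.54; 55 events). The size depended on the window, with every pair counted. It was 13.1 times (11.3 to 15.2) and 2.77 times in the outer 50 kb, and 1.18 times (1.09 to 1.28) and 1.02 times in the outer 200 kb. Events were not counted for these 2 windows, so copies of a few junctions may raise the values, as they did at 100 kb. Subtelomeric sequences are shared between chromosome ends, which limits how surely these ends can be placed. Pairs between the repeat-rich stretches taken for centromeres were 0.979 times (0.717 to 1.31) the random level in the interacting and 1.28 times (1.01 to 1.60) in the de-crosslinked library, and as events 1.25 times (0.790 to 1.87) and 1.09 times (0.751 to 1.53). No excess there was detectable in the interacting library at this depth.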

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

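Pairs 2 to 5 kb apart, which the report's comparisons of pair distances leave out, stood out in the interacting library. They were 85.6 times above the random level there and 48.7 times in the de-crosslinked library, which served as the control. Counted as events, a way of counting chosen after the data were seen, the values were 54.3 and 33.7. Of the pairs under 5 kb, 55.5% in the interacting and 80.1% in the de-crosslinked library lay under 3 kb. No biological explanation was tested for these pairs.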

How the results depend on the processing

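Of 111 values under alternatives, 83 kept their direction and side of the threshold or stayed within their interval. Counting events in place of pairs, the authors' hot class, the repeat-rich stretches taken for centromeres, leaving out the pairs of SPBC359.01 with aat1 or of glm1 with sdo1 and thinning events to the same number were chosen after the data were seen. The lower share of pairs between chromosomes and the higher share within 100 kb in the interacting library kept both under every alternative run. The share of ends in hotspots, interacting less de-crosslinked, of -2.82 points moved to -2.00 counted as events, -1.85 with hotspots also called again from events, -5.25 and -1.07 with hotspots from 5 and 20 times the median, -0.0685 with hotspots from the interacting library, -1.75 from both libraries summed, -2.16 in 2 kb bins, -4.91 for the authors' hot class and -3.24 for that class counted as events. The Pearson r of 0.55 moved to 0.67 counted as events and to 0.73 in 2 kb bins. The 70.0% of summits outside coding genes moved to 84.4% with hotspots called from events, 54.0% from 5 times the median and 87.0% in 2 kb bins. The difference in hotspot pairs within 200 kb, 35.3 points, was 12.6 counted as events (7.25 with hotspots called again), 19.3 without SPBC359.01 with aat1, and was no longer past the threshold in 2 kb bins (1.31), at a limit of 500 kb (7.03; 6.98 as events; but 22.0 and past it without glm1 with sdo1) or from 20 times the median (0, with 1 and 38 pairs left). Hotspot pairs over random fell from 1.87 to 0.888 from 20 times the median, with 9 pairs. The hot less cold difference with distance, -0.45 and within its error, changed sign to 0.17 with identical pairs counted once, 0.52 and 1.11 from 5 and 20 times the median, 0.0783 in 2 kb bins, all within their errors, and to 0.97 and 0.70 for the authors' hot class by pairs and by events, and to 0.61 with these events thinned to the same number, all past the threshold. Centromere pairs, 0.979 times random, moved above 1 as events (1.29 over 200 shuffles) and in 100 kb windows (1.08), within their intervals. Apart from fewer sites or pairs under stricter settings, the cause was not tested. Without the 1% of bins with most ends no hotspot pair was left to count. No analysis paired across strains was made, because only the 2 Rec27-GFP libraries with rec8 present were analysed here. The number of ligation events limits what single pairs of regions can show.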

Other observations

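The tests on copies, on background, on hot less cold within each library, on pairing by GC content alone and on the difference between libraries below were chosen after their results were seen; the tests on single regions, GC content, chance, shared sequence and mixing of libraries were set before.

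Some junctions between distant places were seen in both libraries. Of the junctions between places 20 kb or more apart, 52 had 5 or more pairs in each library. The one with most pairs joined mam3 on chromosome I to map4 on chromosome II, both cell adhesion protein genes, with 94 pairs in the interacting and 66 in the de-crosslinked library. Other paralogs were joined as well: gpd3 with tdh1, both glyceraldehyde-3-phosphate dehydrogenase genes (21 and 25 pairs), pho841 with pho84, both phosphate transporter genes (18 and 27), the ribosomal protein genes rpl501 with rpl502 (11 and 14), and the translation elongation factor genes tef102 with tef101 (12 and 8). Places without such likeness were joined too, such as SPAC17A2.11 on chromosome I with chromosome III near dis1 (91 and 53 pairs), the gap at pdc201 with gpd1 (32 and 36 pairs) and msc1 with med15 (23 and 14 pairs). Closer by on chromosome II, SPBC359.01 and aat1, both of the amino acid permease family, were joined by 326 and 266 pairs across 4317 bp and align over 1459 bp.

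Chance overlap of independent ligations gave a mean of 1.90 such junctions, and at most 5, in 20 random draws of the partners. Sequence shared by the 2 sides was found in 21.2% of the junctions (11 of 52) and in 0 of 300 junctions of 1 library alone, so it may account for the paralogs but leaves the other 41 junctions open. Reads of 1 library assigned to the other at a high rate would carry over most large junctions. Of the 554 junctions with 20 or more pairs in 1 library only 2.71% were seen in the other. A low rate would leave most of them unseen, so this share alone cannot decide on it. Yet a low rate would also give the shared junctions far more pairs in 1 library than in the other. The 52 had counts of the same order in both, such as 94 and 66, 52 and 21, and 5 and 5 pairs in the interacting and de-crosslinked libraries. For these junctions this argues against a low rate, in a reading made after the counts were seen. A rearrangement of the strain against the reference, or DNA shared before amplification, was not tested, and no biological explanation was tested either.

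In the interacting library, joining at 20 to 200 kb, set against joining farther apart or between chromosomes, was higher for hot regions than for cold DNA. With each level taken over random joining, the log2 difference was 0.42 ± 0.08, against -0.21 ± 0.11 in the de-crosslinked library. The 0.70 and 0.56 below are differences between the libraries and hold both. Amplification copies that lie within 500 bp of each other do not account for this, since the log2 excess was 0.70 ± 0.17 with such copies counted once. Copies spread wider than that were not tested. A few hot regions do not supply all of it, as it was 0.56 ± 0.21 without the 20 hot regions with most such events. Within the interacting library alone it then fell to 0.21 ± 0.10 (counting SE), and the control stood at -0.33 ± 0.13. Since the 20 were picked for their events in the interacting library, a fall there was partly set by the choice. Its size therefore does not measure how far a few regions supply the excess. A larger share of randomly ligated background among cold pairs would lower their signal by the same factor at every distance. The hot over cold signal was 1.09 at 5 to 20 kb and 2.11 at 50 to 200 kb, a log2 ratio of 0.95 ± 0.23. This cannot exclude background, because pairs inside 1 hot region are left out, so the hot pairs pooled at 5 to 20 kb lie farther apart than the cold ones. With every pair counted, hot regions were already 32.1 and cold DNA 22.3 times the random level at 10 to 20 kb. The hypothesis that hot regions up to 200 kb apart may be held together in the cell remains open. It rests on 1 library per group, with values found and tested on the same data. Whether Rec27 binds these regions could not be told without an input or untagged library. A replicate culture, or the rec8 deletion libraries, which were not analysed here, would test the hypothesis.

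Between chromosomes, pairs of 1 hot and 1 cold end were fewer than random in both libraries, which random ligation after crosslink removal would not give. The log2 odds ratio of like over unlike ends in the de-crosslinked library was 0.22 ± 0.06 (jackknife SE) with copies counted once, and 0.23 ± 0.06 within classes of like GC content, where hot ends had a median of 36.7% GC and cold ends 36.1%. Hot ends made up 35.2% to 47.1% of the GC classes. With partners redrawn within these classes the log2 ratio had a mean of -0.000516 and was at most 0.0854 in 200 draws. Neither copies within 500 bp of each other nor pairing by GC content therefore accounts for the log2 odds ratio seen. In the interacting library it was 0.42 ± 0.08, and the difference between libraries of 0.19 ± 0.10 leaves open whether hot and cold DNA were kept in separate pools to the same degree in both: it met the bar first set for that, a 95% interval holding 0, but not a stricter one set after the value was seen, an upper bound below the de-crosslinked value. DNA still held together after the heat step could give the de-crosslinked value, and no test here separates it from other causes.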
